A study of Mus musculus with 6 samples.

How the data were processed

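RNA was measured in whole mouse hearts at embryonic day 9.5, in 3 control libraries and 3 libraries from hearts with a myocardial Cdc42 knockout (MCKO). Per the labels' protocols, RNA was isolated with the Aurum Total RNA Mini Kit and libraries were made with a stranded TruSeq mRNA kit. The deposited values are estimated counts per Ensembl gene, as whole numbers, not normalized for depth or gene length. Per the submitters' processing notes, kallisto, which assigns reads to transcripts, and the mouse build mm10 were used, with no version or role given. The transcript set, the summing of transcripts to genes and the rounding are not given in the sources used here. Reads that match several near-identical transcripts are divided between them in such estimates, so genes with a near-identical copy are named as such.

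The control columns of the table carry the sample titles. The knockout columns are named CKO where the titles have MCKO, and were matched by the rest of the name and the number. The table held 30323 gene IDs, of which 29857 matched a gene symbol, and the other 466 took 0.201 to 0.232% of the counts of a library. The library totals were 26983608, 19256840 and 32169289 counts for control replicates 1, 2 and 3, and 34246477, 25712499 and 23883877 counts for MCKO replicates 1, 2 and 3. At these depths 3 counts in a library correspond to 0.0876 to 0.156 CPM (counts scaled to the library total), the most that a count of 0 allows. Floors and counting intervals cover counting error only, since no molecular identifiers are named in the labels. Gene coordinates came from GENCODE release M21 on GRCm38, the assembly also called mm10.

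The groups were compared with edgeR 4.0.16 in R 4.3.3: default filterByExpr, TMM normalization, robust quasi-likelihood fits with group as the only term, 2-sided tests and Benjamini-Hochberg adjustment over 14697 tested genes. A gene was called at an adjusted p under 0.05. Log2 fold changes are MCKO over control with their standard errors (SE), while CPM values are shares of each library's total and are given as mean ± SD over the 3 libraries of a group. The series' design text gives 3 hearts per set, but the labels do not tie each library to one heart or to a litter. The p-values therefore measure only the spread between these samples, which may be technical.

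A set of 30 gene lists was written before the data were examined, together with the tests and the alternatives. Lists were tested with camera in limma 3.58.1, with a preset correlation of 0.01 between genes, and again with an estimated correlation, both adjusted over the lists. The fry test, which asks whether the genes of a list move on balance one way and does not compare them with other genes, was run beside them. With an estimated correlation camera also uses only the few residual degrees of freedom of the 6 libraries. Its p-values are then larger even where the correlation is not. Of the symbols on the lists, 6 were not found in the table, Xist among them. The text names Cdc42, then genes from 3 rules fixed beforehand. The first takes the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM whose groups do not overlap, leaving out predicted genes, unnamed IDs and sex-linked genes. The others take up to 4 called members of each list by smallest p (or, where none is called, the 1 with the smallest p), and the 5 most abundant called genes in each direction. Some genes that these rules take are not reported here. Genes named outside these rules are said to have been chosen after their values were seen.

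The test was tried on simulated counts drawn from the real means, depths and dispersions, with 50 genes changed at each of 4 sizes. It recovered 24% of the genes changed by 0.25 on the log2 scale and 72% at 0.5, among 14524 genes tested. At 1 and 2 it recovered 92% and 98%. It made 13 false calls, 8.33% of its calls, which is above the nominal rate of 0.05. Far fewer genes changed there than the 8587 called in the real data, which makes the adjusted threshold stricter in the simulation. The recovery rates therefore do not describe the real comparison. In simulated lists among 14697 genes, camera called the shifted list and neither the balanced list nor any of 28 unchanged lists. The simulated genes were drawn independently, so false list calls from correlation between genes could not arise. In the real data the estimated correlation was 0.237 for the list of oxidative phosphorylation and mitochondria and 0.808 for the 4 sex-linked genes. Replicates were compared by a chi-square statistic per degree of freedom, which was 3.58 to 15.4 within groups and 90.7 to 143.6 between groups, so no library was taken for a copy of another.

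Near-identical copies were found by mapping the longest transcript of each gene to all others with minimap2 2.31, at 95% identity over 80% of the length. The alternatives were other size factors, library totals only, no filter or at least 50 counts in 3 libraries, DESeq2 1.42.0, limma-voom, a replicate block, each library left out in turn, red cell genes left out, a 2-fold minimum and an adjusted p under 0.01. A GC correction, leaving out pseudogenes and copies, leaving out mitochondrially encoded genes, and a covariate from Y-linked genes were added after seeing the data. The planned sex score was not run, because it needed Xist, which is not analysed here.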

Results

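RNA abundance in whole hearts of mouse embryos at embryonic day 9.5 was compared between controls and embryos in which the small GTPase gene Cdc42 was deleted in the myocardium (MCKO). At this stage the heart tube is looping, and its muscle wall and endocardium are separated by cardiac jelly. Each group had 3 libraries, with 19256840 to 32169289 estimated counts in controls and 23883877 to 34246477 in MCKO, and CPM values are counts scaled to these totals. The comparison asks which transcripts of the heart differ when its muscle lacks Cdc42.

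Cdc42 itself was lower in every MCKO library than in every control library. The controls held 398.8, 377.3 and 423.7 CPM and the MCKO libraries 247.6, 240.8 and 238.5 CPM. The log2 fold change was -0.66 (SE 0.047, edgeR adjusted p = 2.93e-06). Cdc42 (ENSMUSG00000006699) is a protein-coding gene on the minus strand of chromosome 4 at 137319696 to 137357720 in GRCm38. The hearts were whole, so other cell types contribute Cdc42 reads, and which exon was deleted is not given in the labels.

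Most tested genes differed between the groups. By edgeR, 8587 of 14697 tested genes (58.4%) were called, 4308 higher and 4279 lower in MCKO. Of the calls, 53.2% were smaller than 0.5 on the log2 scale, and 1033 genes were at least 2-fold higher and 586 at least 2-fold lower. The groups did not overlap for 65.5% of the tested genes, where chance gives 10%. The first principal component held 75.0% of the variance and separated the groups, and the common biological coefficient of variation within groups was 7.31%. The labels give no batch, date or read length for the libraries, so a batch or a processing step that follows the groups was not tested.

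Among the largest rises were Trib3, a pseudokinase induced by ATF4, Chac1, a glutathione-degrading enzyme, and Ndrg1, a hypoxia-induced gene. Trib3 went from 2.20 ± 0.13 to 74.6 ± 3.3 CPM (n = 3 each), Chac1 from 0.503 ± 0.062 to 24.97 ± 1.27 CPM and Ndrg1 from 4.28 ± 0.65 to 89.6 ± 0.49 CPM. Ndufa4l2, a hypoxia-induced mitochondrial protein gene, had a log2 fold change of 6.05 (SE 0.15), and Apln, the ligand of the apelin receptor, 4.45 (SE 0.13). Sncb, which encodes beta-synuclein, had 3 counts over the control group and 921 over the MCKO group, a ratio of 287 with a 95% counting interval of 97.9 to 1395. The largest falls included genes with and without a near-identical copy. Ftl1-ps1, a near-identical copy of the ferritin gene Ftl1, went from 129 ± 10 CPM to 0 counts, at least 3567-fold lower against a floor of 3 counts over the group. The retrocopies Ftl2-ps and Pcna-ps2 also fell to near 0, and their values are uncertain because estimated counts can move between copies. Tpm3-rs7, a tropomyosin-related gene without a near-identical copy by the criteria used here, went from 155 ± 3.4 to 0.366 ± 0.166 CPM. It fell to near 0 as the retrocopies did, and a copy that the criteria miss was not excluded, so its value is uncertain too. Among other falls without a near-identical copy, Postn, a matrix protein of cushion mesenchyme, went from 32.9 ± 0.76 to 3.59 ± 0.66 CPM. Aldh1a1, a retinaldehyde dehydrogenase, went from 12.98 ± 0.64 to 1.07 ± 0.060 CPM.

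**Figure D1:**
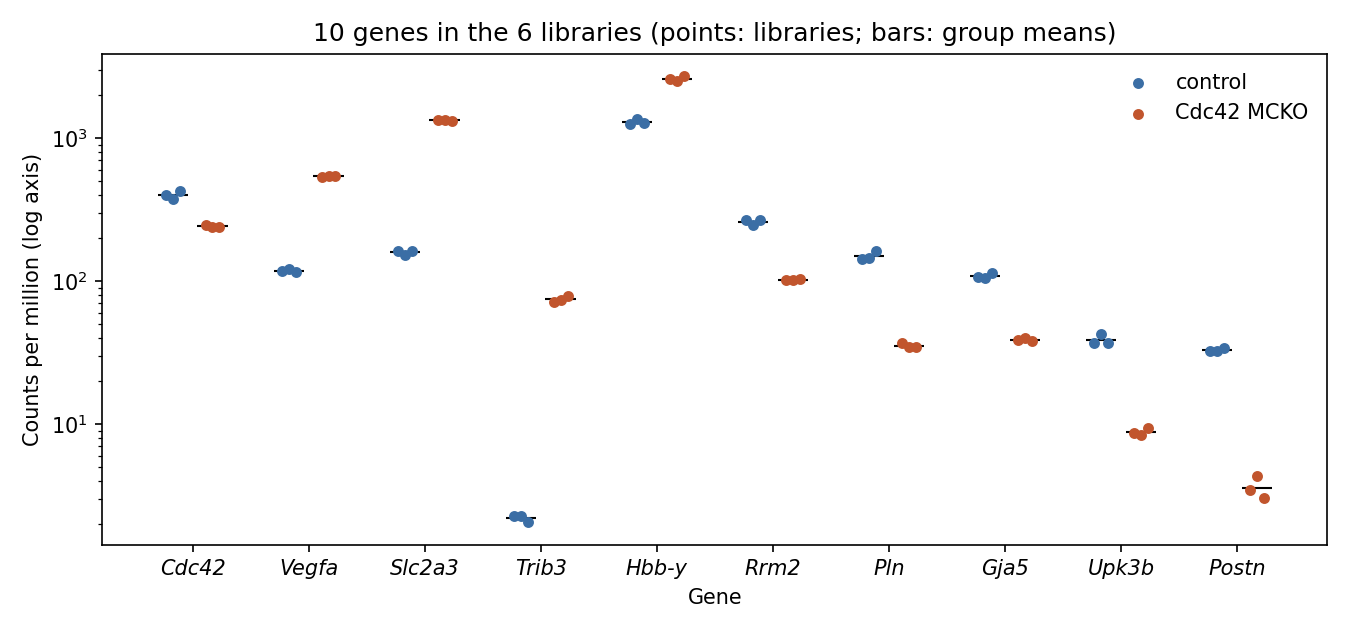
CPM on a log axis for 10 genes in the 3 control and 3 Cdc42 MCKO libraries; points are libraries and bars are group means. For each of the 10 genes the groups do not overlap, as for Cdc42 with 377.3 to 423.7 CPM in controls and 238.5 to 247.6 CPM in MCKO.

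Genes of the hypoxia response and glycolysis were higher in MCKO almost throughout. Of 32 measured members, 31 rose and 1 fell, with the same counts when adjusted over the list alone, and the median log2 fold change was 1.64. Slc2a3, a glucose transporter, rose from 159 ± 5.8 to 1340 ± 15.6 CPM, and P4ha2, a collagen prolyl hydroxylase, from 49.0 ± 1.3 to 327 ± 3.5 CPM. Vegfa, the main endothelial growth factor, rose by 2.26 (SE 0.042) and Bnip3, a mitophagy receptor with a near-identical copy, by 2.60 (SE 0.047). The member that fell was Eno1, an enolase gene with a near-identical copy, named after its value was seen. The camera test called the list (adjusted p = 5.52e-16), with adjusted p = 0.0519 with an estimated correlation. In the same libraries the haemoglobin genes took 0.697 to 0.749% of counts, against 0.320 to 0.361% in controls.

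The integrated stress response slows translation and induces amino acid genes. Genes on the list of this response and of unfolded proteins were higher too. Of 28 measured members, 23 rose and 3 fell, also when adjusted over the list alone, with a median of 1.63. Vldlr, a lipoprotein receptor, rose from 31.0 ± 0.98 to 231 ± 4.9 CPM and Stc2, a secreted glycoprotein, from 7.92 ± 0.82 to 102 ± 3.5 CPM. The adjusted p was 1.87e-09 by camera, with adjusted p = 0.0519 with an estimated correlation. Of 30 immediate early and heat shock genes, 24 rose and 3 fell, over all genes and adjusted over the list alone, with a median of 1.23. Ier3 rose from 4.48 ± 0.36 to 68.8 ± 3.6 CPM and the transcription factor gene Nr4a1 from 14.8 ± 1.0 to 46.5 ± 1.5 CPM. For this list the camera adjusted p was 1.24e-05, with adjusted p = 0.0688 with an estimated correlation. Primitive red cell genes were higher in the same libraries, with a median of 0.94.

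Transcripts of red cells and of endothelium were more abundant in MCKO. Of 28 primitive red cell genes, 26 rose and none fell (26 and 1 when adjusted over the list alone), with a median of 0.94. The embryonic globin Hbb-y went from 1293 ± 52 to 2605 ± 93 CPM and Alas2, which starts haem synthesis in red cells, from 30.1 ± 1.1 to 60.5 ± 0.52 CPM. The camera adjusted p was 1.35e-08, with adjusted p = 0.0688 with an estimated correlation. Of 32 endothelial and endocardial genes, 23 rose and 3 fell (24 and 3 when adjusted over the list alone), with a median of 0.47. Flt1, a VEGF receptor, rose from 67.1 ± 1.6 to 165 ± 1.8 CPM and Sox17, an endothelial and endodermal transcription factor, from 4.14 ± 0.55 to 18.6 ± 1.6 CPM. Gpr182 fell from 43.9 ± 0.51 to 21.6 ± 0.79 CPM. The camera adjusted p was 4.23e-05, with adjusted p = 0.0688 with an estimated correlation.

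Cell cycle genes were lower, mostly by small amounts, with 2 members at least 2-fold lower. Of 39 members, 29 fell and 1 rose, also when adjusted over the list alone, with a median of -0.24. Rrm2, a subunit of ribonucleotide reductase, went from 259 ± 12 to 102 ± 0.59 CPM, Ccne1, which drives entry into S phase, from 56.5 ± 0.94 to 26.8 ± 1.2 CPM, and the replicative helicase gene Mcm4 from 218 ± 1.1 to 130 ± 2.4 CPM. The camera adjusted p was 1.24e-05, with adjusted p = 0.0519 with an estimated correlation. Of 40 genes of oxidative phosphorylation and mitochondria, 27 fell and 5 rose, also when adjusted over the list alone, with a median of -0.22. Ogdh, an enzyme of the citric acid cycle, went from 484 ± 10.2 to 250 ± 4.6 CPM, and the complex I gene Ndufs1 from 309 ± 10.4 to 205 ± 4.8 CPM. This list had a camera adjusted p of 0.00237, with adjusted p = 0.51 with an estimated correlation. The red cell and endothelial lists were higher in the same libraries, with medians of 0.94 and 0.47.

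Retinoic acid and Hox genes were higher: 14 of 22 rose and 1 fell, also when adjusted over the list alone, with a median of 0.65. Cyp26a1, which degrades retinoic acid, rose from 0.654 ± 0.175 to 4.58 ± 0.27 CPM. The camera adjusted p was 0.0033, with adjusted p = 0.0926 with an estimated correlation. In the same libraries red cell and endothelial genes were higher, with medians of 0.94 and 0.47, and all 13 measured pharyngeal endoderm genes, a list partly picked after values were seen, rose. With an estimated correlation, none of the 30 lists passed 0.05, and 8 passed with the preset one.

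Heart muscle genes went both ways, and their lists were not called by camera. Of 39 sarcomere genes, 19 rose and 8 fell (camera adjusted p = 0.212), among them Myh7, a myosin heavy chain, which went from 6332 ± 449 to 10131 ± 306 CPM. Actc1, cardiac actin, rose by 0.23 (SE 0.044), while Myoz2, a Z-disc protein, went from 12.4 ± 1.3 to 3.68 ± 0.54 CPM. Of 31 genes of calcium handling and ion channels, 16 rose and 12 fell (camera adjusted p = 0.629), and the median of 0.17 differed in sign from the mean of -0.13 and from fry. Pln, the inhibitor of the calcium pump SERCA, went from 150 ± 11.5 to 35.4 ± 1.4 CPM. Of 31 cardiac transcription factor genes, 12 rose and 6 fell (camera adjusted p = 0.333), with Tbx5 at a log2 fold change of 0.59 (SE 0.041) and Hand2 at -0.71 (SE 0.064).

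Genes of signals between endocardium and muscle went both ways. Of 26 genes of trabeculation, the growth of muscle ridges into the ventricle, 12 rose and 9 fell (camera adjusted p = 0.56). Gja5, the connexin of trabecular muscle, went from 108 ± 4.9 to 38.9 ± 1.1 CPM, while Nppb, a natriuretic peptide gene, went from 82.6 ± 3.8 to 133 ± 3.1 CPM. Nrg1, named after its values were seen, is one of 8820 gene IDs listed at 0 in all 6 libraries. The transcript set is not given, so an ID that was not quantified cannot be told from a gene without reads. Of 25 Notch pathway genes, 14 rose and 8 fell (camera adjusted p = 0.212). The ligand gene Dll4 rose from 16.4 ± 2.1 to 43.9 ± 2.0 CPM and the receptor gene Notch4 from 20.6 ± 1.4 to 55.6 ± 3.8 CPM, whereas the ligand gene Dll1 fell from 6.75 ± 0.54 to 1.48 ± 0.25 CPM. Endothelial genes were higher in the same libraries, with a median of 0.47.

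Of 34 genes of cardiac jelly and extracellular matrix, 17 fell and 11 rose (camera adjusted p = 0.212, median -0.14). The fibrillar collagen genes Col3a1 and Col1a2 went from 273 ± 6.3 to 78.1 ± 1.7 CPM and from 90.7 ± 4.2 to 27.8 ± 0.34 CPM, and Tnc, tenascin C, from 201 ± 5.4 to 90.2 ± 2.2 CPM. Of 18 genes of the epicardium and proepicardium, the cell layer that comes to cover the heart, 10 fell and 5 rose (camera adjusted p = 0.111, median -0.57). Upk3b went from 38.8 ± 3.3 to 8.82 ± 0.56 CPM, Lrrn4 from 32.9 ± 2.3 to 5.12 ± 0.44 CPM and Tbx18 from 63.1 ± 1.5 to 22.8 ± 0.93 CPM. Krt19, a keratin of several epithelia, rose from 42.6 ± 3.1 to 395 ± 25.1 CPM.

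Regulators and effectors of Cdc42 and the actin genes went both ways, and their lists were not called. Of 51 Cdc42 partners, 16 rose and 8 fell (camera adjusted p = 0.456), the related GTPase gene Rhoq by 0.71 (SE 0.051) and Rhoa by 0.39 (SE 0.040). Of 36 genes of actin filaments and filopodia, 10 rose and 7 fell (camera adjusted p = 0.629), with Vasp at 0.53 (SE 0.040) and Eps8 at -0.60 (SE 0.066). Of 35 genes of cell junctions and polarity, 17 rose and 8 fell (camera adjusted p = 0.212). Lims2, an adaptor at integrin adhesions, rose from 3.04 ± 0.51 to 24.02 ± 0.61 CPM.

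The other signalling lists were not called by camera either. Among p53 targets and cell death genes 13 of 25 rose and 6 fell (adjusted p = 0.0994), with Cdkn1a, a cell cycle inhibitor, at 1.80 (SE 0.069) and Aen at -0.94 (SE 0.051). Among YAP and SRF targets 14 of 27 rose and 4 fell (adjusted p = 0.0994), with Ccn2 at 1.67 (SE 0.063). Among second heart field and outflow tract genes 14 of 23 rose and 7 fell (adjusted p = 0.156), with Fgf10 at 1.55 (SE 0.085) and Sema3c at -1.17 (SE 0.064). Among BMP and TGF-beta genes 17 of 35 rose and 7 fell (adjusted p = 0.209), with Bmpr1b at -2.26 (SE 0.16). Among Wnt genes 15 of 32 rose and 12 fell (adjusted p = 0.855), with a median of 0.13 and a mean of -0.07.

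Markers of tissues around the heart moved in both directions within lists, none of them called by camera in the main analysis. Of 26 genes of foregut endoderm, liver bud and yolk sac, 13 rose and 9 fell (adjusted p = 0.517). Their median of 0.68 and mean of -0.31 differed in sign. The median depended on the filter, at 0.059 without one and 1.22 with the stricter one, where camera called the list (adjusted p = 0.0454). Afp, alpha-fetoprotein, went from 11.4 ± 0.90 to 0.1003 ± 0.0903 CPM, while Epcam, an epithelial adhesion molecule, went from 0.898 ± 0.091 to 5.41 ± 0.41 CPM. In surface ectoderm 6 of 11 genes rose and 3 fell (adjusted p = 0.517). In neural crest and mesenchyme 7 of 25 rose and 9 fell (adjusted p = 0.781), and Sox9 went from 30.6 ± 0.67 to 12.8 ± 0.43 CPM. The median of this list, 0.07, differed in sign from camera, but it ran from -0.072 to 0.118 with each library left out. In neural tube 5 of 13 rose and 3 fell (adjusted p = 0.923, median -0.11, mean 0.13), and Tubb3, a neuronal tubulin, went from 23.4 ± 2.9 to 4.39 ± 0.74 CPM. In macrophages and other leukocytes 2 of 13 rose and 4 fell (adjusted p = 0.665). Of 21 strain-variable genes 7 rose and 6 fell (adjusted p = 0.981), and of 4 Y-linked genes only Kdm5d was called, at -0.24 (SE 0.074), a call lost in 3 alternative fits (adjusted p = 0.0516 to 0.0741).

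**Figure D2:**
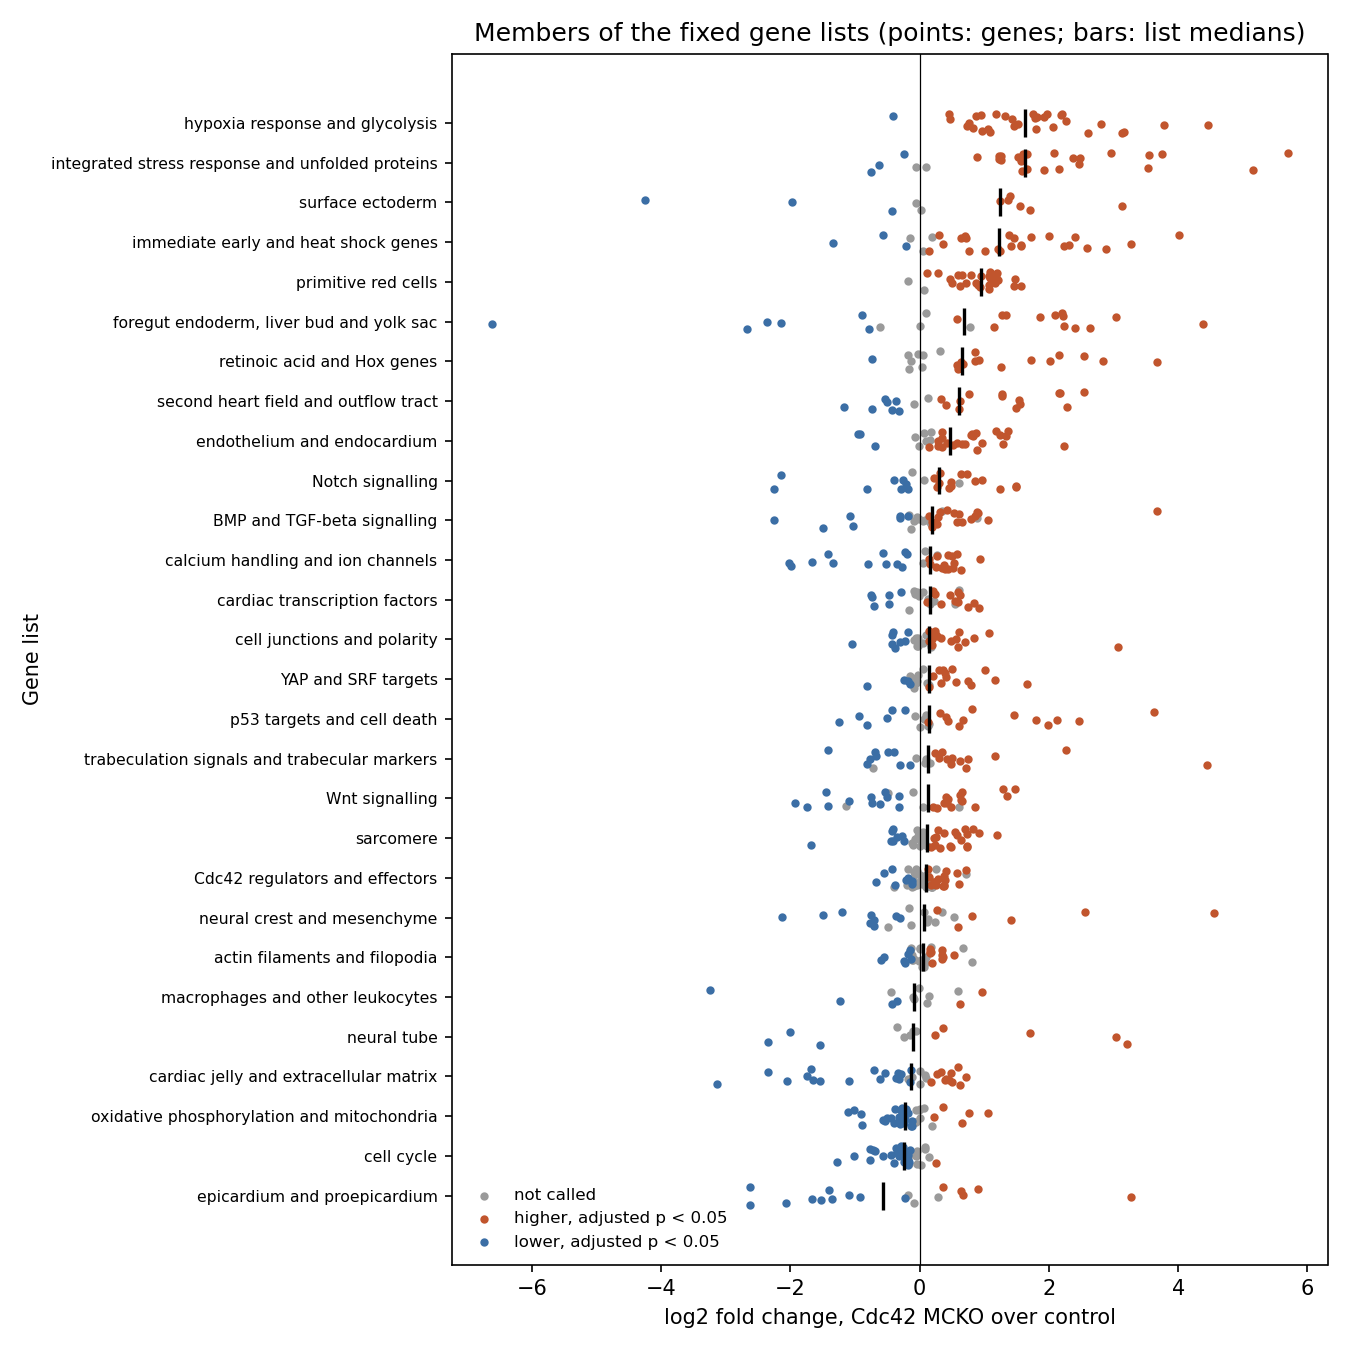
Log2 fold change of MCKO over control for the measured members of the fixed lists, with points as genes coloured by their edgeR call and bars as list medians. The hypoxia and integrated stress lists have the highest medians, 1.64 and 1.63; the sex-linked and strain-variable lists, and genes with at most 3 counts over a group, are not drawn.

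The most abundant transcripts that differed included mitochondrially encoded ones. The cytochrome oxidase gene mt-Co1 went from 9954 ± 333 to 4025 ± 112 CPM and the cytochrome b gene mt-Cytb from 4165 ± 215 to 1409 ± 30.6 CPM, and mt-Co1 has near-identical nuclear copies. Mitochondrially encoded genes took 3.13 to 3.55% of counts in controls and 1.31 to 1.38% in MCKO. Gapdh, a glycolytic enzyme, went from 3672 ± 171 to 5854 ± 150 CPM, and Mest, an imprinted gene, from 3065 ± 159 to 2042 ± 49 CPM.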

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

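The GC correction, the settings without pseudogenes or without mitochondrially encoded genes, and the Y-linked covariate were chosen after seeing the data. Cdc42 stayed lower and called under all 18 alternatives, from -0.72 to -0.59 on the log2 scale, with adjusted p from 3.64e-34 to 0.000119. At an adjusted p under 0.01, 6664 genes were called, and in the settings that kept the threshold the count was 7452 to 9368, and leaving out each library in turn gave 7452 to 8695. With at least a 2-fold change, 1619 genes were called, 1033 higher and 586 lower, by construction fewer. With library totals only, 42.6% of the calls were higher, against 50.2% with TMM. With the replicate block, 7765 genes were called and every list call stood; the correlations of deviations between same-numbered libraries were -0.078, 0.053 and -0.225, and not every library correlated best with its own number. Of the 30 lists, 8 were called in each leave-one-out setting and 0 with an estimated correlation. That setting replaces the preset correlation between genes with one measured in 6 libraries. It also lowers the degrees of freedom of the test to the few that these libraries leave, which raises p even at the same correlation. The estimate was -0.0033 for the cell cycle list, -0.0055 for retinoic acid and Hox genes and 0.0097 for the endothelial list, all below the preset 0.01. A higher correlation between genes therefore does not account for the loss of these calls. Of the named genes, the only calls lost were those of Kdm5d in 3 fits and Hsp90ab1 in 4, each with its direction kept. Without a filter the p53, YAP and SRF, and epicardium lists were called (adjusted p = 0.0136, 0.0314 and 0.0344), and with the stricter filter the foregut list was (adjusted p = 0.0454, median 1.22, against 0.059 without a filter).

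Lists that were called in neither setting changed direction in 15 cases, given here by their median log2 fold change, which need not follow camera's direction; the cause was not tested. With the GC correction these were trabeculation (0.045), Wnt (0.064) and sex-linked genes (0.080). Without a filter they were neural crest (0.19), neural tube (0.35) and strain-variable genes (0.015). With library totals only they were neural tube (-0.17) and strain-variable genes (-0.054), and with the replicate block strain-variable genes (0.0062). Leaving out control replicate 1 did so for neural tube and leaving out control replicate 3 for the sex-linked genes, while 4 of the 6 libraries did so for strain-variable genes. Over all leave-one-out settings the medians ran from -0.178 to -0.067 for neural tube and from -0.056 to 0.115 for the sex-linked genes. They ran from -0.062 to 0.137 for strain-variable genes and from -0.072 to 0.118 for neural crest and mesenchyme. The depth sets a floor: a count of 0 allows up to 0.0876 to 0.156 CPM in a library. In data simulated with these depths, spreads and 3 libraries per group, 24% of genes changed by 0.25 were recovered, and depth was not varied. Far fewer genes changed in that simulation than were called in the real data, so this rate does not carry over to the real comparison.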

Other observations

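The lists and genes in this part were chosen after their values were seen, so they are no independent evidence. Of 13 mitochondrially encoded genes 11 fell and none rose, and of 24 proteasome genes 22 fell and none rose, with medians of -1.24 and -0.36. Of 23 genes of the cholesterol synthesis list 15 fell and none rose, among them Hsd17b7, which went from 59.9 ± 6.2 to 18.99 ± 1.58 CPM. Of 20 cytosolic aminoacyl-tRNA synthetase genes 12 rose and 6 fell, with Sars from 112 ± 4.5 to 268 ± 2.5 CPM and Hars from 106 ± 2.4 to 66.3 ± 1.9 CPM. Camera with the preset correlation called these 4 lists (adjusted p = 4.85e-07 for the proteasome), and with an estimated correlation none of the 4 passed (adjusted p = 0.0557 to 0.368).

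Of 15 collagen-modifying enzyme genes 9 rose and 3 fell; Plod2 went from 87.2 ± 3.1 to 258 ± 11.8 CPM and Loxl2 from 362 ± 8.2 to 921 ± 15.9 CPM. Of 13 genes of the major histocompatibility complex 7 rose and 1 fell, with H2-K1 from 3.36 ± 0.40 to 41.0 ± 1.5 CPM and H2-Ab1 from 3.64 ± 0.22 to 48.4 ± 0.83 CPM, while H2-D1 was 5.89 ± 0.74 and 6.35 ± 0.70 CPM. All 9 measured liver bud genes fell: Fgb and Alb had 0 counts in MCKO and were at least 42.4-fold and 28.9-fold lower against 3 counts over the group. All 13 measured pharyngeal endoderm genes rose, with Pax9 from 0.0765 ± 0.078 to 2.10 ± 0.38 CPM. The liver bud and pharyngeal lists were partly picked from genes already seen to move, so their camera adjusted p (0.0346 for each with an estimated correlation) says nothing of their direction. With an estimated correlation the adjusted p was 0.238 for collagen-modifying enzymes and 0.0831 for the histocompatibility list.

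In the following tests, only the GC correction, the stage genes and the other splits were set before their results were seen; the rest were chosen after. The other 9 splits of the 6 libraries into 3 and 3 called 0 genes by edgeR (31 to 283 at an unadjusted p under 0.05), against 8587 for the real one. Only 1 of the 10 splits, the real one, called that many, and 10 splits are too few for a share under 0.05. Every other split mixes the groups, so the group difference counts as spread within each side and few calls were bound to follow. The splits therefore say little about chance.

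The first pattern is the rise of hypoxia and integrated stress genes. After a GC correction the hypoxia median was 1.71, above the bound of 1 set beforehand, which argues against a GC trend as the whole cause. More blood in the hearts is argued against too, but only as the whole cause, since red cell genes did rise. The hypoxia median exceeded the red cell median by 0.69, with a bootstrap SE of 0.25. The bootstrap draws genes, which are not independent, and not embryos. Longer handling of the knockout hearts before lysis stays open. The immediate early list had a median of 1.23 and a camera adjusted p of 1.24e-05 with the preset correlation. The rule also asked for a call with an estimated correlation, which none of the 30 lists reached, so it could not decide. A low oxygen supply in the embryos, which may also raise these genes, was not tested separately.

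The second pattern is gene copies near 0 in one group, taken as at most 3 counts in every library of that group and at least 30 in every library of the other. Of 19 such genes, 14 near 0 in MCKO and 5 in controls, 47.4% had a near-identical copy, against 8.15% of tested genes. This is short of the majority asked of reads divided differently between copies, so that explanation stays open. The criteria can miss copies: Gm6969 and Gm11868, both annotated as processed pseudogenes, counted as having none. The test was first coded on the genes near 0 in MCKO alone, where 9 of the 14 had a copy, while 0 of the 5 near 0 in controls had one. It was then recoded to match the written prediction, which takes genes near 0 in either group. Loss of the copies with the parent unaffected stays open as well: the median log2 fold change of 7 parents was 0.19, with 4 above 0 (sign test, exact 2-sided p = 1). The test cannot tell loss from moved reads where a copy is small beside its parent. In controls Gm2427 had 2.41 CPM and its parent Arhgef12 173 CPM, though Ftl1-ps1 had 129 CPM and Ftl1 606 CPM. The parent Bnip3, at 2.60, is also on the hypoxia list that rose. A genetic background that differs between groups may contribute: the median absolute change of 21 strain-variable genes lay at the 97.3 percentile of 10000 lists matched on expression. The labels give neither strains nor read lengths, so background and a processing difference that follows the groups were not separated from the knockout.

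The third pattern is that markers of neighbouring tissue moved. A lower share of heart muscle would raise the markers of all other cell types alike, and the tables argue only weakly against it as the whole cause. The medians of the 8 fixed lists of other cell types had a weighted SD of 0.51, against 0.25 for permuted lists (permutation p = 0.0022, across genes, which are not independent), and the sarcomere median was 0.11. This test replaced earlier versions. These used the liver bud list, picked after its values were seen, and then the epicardium median alone. The epicardium median, -0.57 with a bootstrap SE of 0.52, had not decided. A test adopted after such attempts is weak evidence. An earlier developmental stage of the knockout hearts stays open, with a median of 0.22 over 8 genes that fall during midgestation, 4 of them higher and 3 lower, between the bounds of 0 and 0.3. Neither the dissection of the hearts from liver bud and pharynx nor a change in these tissues in MCKO was tested.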
